A study of Mus musculus with 28 samples.

How the data were processed

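The series holds 28 mouse samples, and values from 10 of them were analysed: 5 mRNA libraries, 4 microRNA libraries and 1 library of single-stranded DNA, all from testis of C57BL/6 mice per the labels. The other 18 samples, which are libraries of trimethylated histone H3 lysine 4 and an input from testis and from the GC-1 germ cell line, were not analysed here. Groups and replicate numbers came from the genotypes and titles in the labels. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. For microRNAs this spread was pooled over all that were tested. No age is given for the knockout mice, whereas the wild-type library is labelled adult. No column of per-sample values was left unused (0 columns), and no pair of mRNA libraries shared an identical value above 0.

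The mRNA values are a signal of abundance for 34839 genes that the authors called TPM, a share of transcripts, per the file headers. Per the submitters' processing notes, CASAVA, kallisto and sleuth were used with builds GRCm38 and mm10. Their versions and the transcript set are not given in the sources used here. The columns sum to 873316 and 825459 in the Prdm9 knockouts, 896480 and 953598 in the Hop2 knockouts and 1622660 in wild type, where plain TPM would sum to 1000000. Division by size factors would give such sums, but the factors are not given in the sources used here. Such a value keeps no read depth, so the depth of these libraries is unknown. The planned test on the log2 scale was kept. The transcript table holds the same values per transcript for 109282 transcripts, and gene values equalled the sums over transcripts within 2.2e-11.

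The microRNA values are likewise a signal called TPM, per the file headers, in 2520 lines for 1915 mature names, with a mature microRNA repeated for each precursor. Per the submitters' processing notes CASAVA and DESeq2 were used by the authors, and the aligner is not given in the sources used here. Columns sum to slightly over 1000000 over all lines, values are rounded to 2 decimals and whole reads could not be recovered, so a count model was not run and depth is unknown. Each mature name was used once, but 10 tested names share all values with another, as reads entered under more than 1 name would give. The authors also deposited p-values and q-values of their own gene test (sleuth) and, for microRNAs, adjusted p-values and log2 fold changes (DESeq2). The compared groups are not named in either table. The residuals of the deposited gene table match a fit of 4 libraries, and the log2 signs of the deposited microRNA table follow Prdm9 knockout minus Hop2 knockout.

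Values were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate changes of weakly expressed genes. Genes with a mean of at least 1 over the fitted libraries were tested (at least 10 for microRNAs). Prdm9 and Hop2 knockouts were compared in a fit of the 4 knockout libraries. Both comparisons with wild type came from a fit of all 5 mRNA libraries, in which the single wild-type library is assumed to vary like the knockouts. Gene lists were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation. Lists needed at least 5 tested genes (3 for microRNAs). With an estimated correlation camera also takes only the few residual degrees of freedom of the fit. Its p-values then rise even without correlation between genes, so a lost call does not show that correlation made the call.

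The gene lists cover the targeted genes, early meiotic prophase, genes switched on at pachytene, spermatids, spermatogonia, Sertoli cells, Leydig cells, myoid cells, macrophages, endothelium, red blood cells, epididymis, p53 targets, DNA repair, the piRNA pathway, Y-linked genes, the cell cycle and H3K4 methylation. The microRNA lists cover the miR-34 and miR-449, X-linked, miR-17-92, miR-290, let-7, Dlk1-Dio3, miR-29, miR-30 and miR-200 families, and microRNAs of muscle, endothelium, immune cells, red blood cells and Sertoli cells. Meiosin and Prdm7 matched no gene identifier and were not analysed here. The lists, the tests, the alternatives and the naming rule were fixed before the data were examined, except where said otherwise.

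Named genes follow a fixed rule. Prdm9, Psmc3ip and Morc2b come first. For each mRNA comparison the rule takes up to 10 genes per direction with the largest fold change past the threshold and without overlap between groups, filled where few pass by those of smallest unadjusted p up to 5, and skips predicted genes, clones and pseudogenes. Clone-based names were treated as clones, and the filling step was brought to the fixed wording after values had been seen. From each list the rule takes the members with the largest absolute fold change, 4 where the list passed, 2 where it did not and 3 for microRNAs. The text names some of these. For the break map the rule asked for the peaks of highest score, and since the peak list holds no score, peaks were ranked by distinct fragments instead. The gene-end peak with most fragments is not reported here.

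Single-stranded DNA sequencing (SSDS) recovers single-stranded DNA bound by strand exchange proteins at meiotic double-strand breaks. The authors deposited the coordinates of fragments classed as type 1, the most confidently single-stranded class, and a list of peaks of this 1 library. MACS2 2.1.0.20150420 is named per the submitters' processing notes. The deposited files hold coordinates and strand and no signal or coverage values. They give 9397213 fragment lines, of which 2652951 (28.2%) were distinct in start, end and strand. Each peak was compared with gene positions of the RefSeq annotation of GRCm38.p6, the build family the submitters name. The annotation table used has no strand, so a start site could not be told from a gene's other end: "at a gene end" means within 1000 bp of either end of a protein-coding gene. This either-end rule and the limit to protein-coding genes were chosen when coordinates were first joined, not beforehand. Peaks were placed at random 1000 times on their own chromosomes, and binomial intervals are exact at 95%. They cover counting error only, since amplified copies of a fragment are not independent molecules. Of 21887 protein-coding genes in the annotation, 20597 matched the mRNA table.

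The limma fits, 1 camera test and the joining of peaks to gene ends were tested on simulated data, and other steps were not. For Prdm9 knockout against Hop2 knockout (14358 genes, 200 changed), 67.2% of genes changed by 1 on the log2 scale, 98.5% by 2 and 97.0% by 3 were recovered, with 8.38% of calls false. For Prdm9 knockout against wild type (16261 genes, 200 changed) 20.9%, 82.1% and 95.5% were recovered, and for Hop2 knockout against wild type (200 changed) 25.4%, 79.1% and 90.9%. In the data limma called 12043 and 12110 genes in these comparisons, so the rates for few changed genes need not hold there. For microRNAs (339 tested, 67 changed) 8.70%, 72.7% and 95.5% were recovered. In the simulated 14358 genes, camera called a set of 400 genes moved by 0.2 and did not call an unmoved set of 400. These genes were simulated independently of each other, so lists of correlated genes were not covered. Alternatives covered the pseudocount, the filter, the scaling, the variance trend, the libraries in the fit, each library left out, the correlation between genes, the window at gene ends and the peaks and fragments used. Plots were drawn with matplotlib 3.10.9, and other sums used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.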

Results

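The series addresses what the parts of PRDM9, the histone methyltransferase that places meiotic recombination hotspots, do in meiosis. Testis mRNA was measured in 2 Prdm9 knockout (KO) libraries, 2 Hop2 KO libraries and 1 adult wild-type library, and microRNA in 2 Prdm9 KO and 2 Hop2 KO libraries. Meiotic double-strand breaks were mapped by SSDS in 1 testis library of mice whose PRDM9 lacks its KRAB domain (Prdm9 K/K). Hop2, with the approved symbol Psmc3ip, encodes a cofactor of DMC1 in strand exchange. Values of mRNA are given in the authors' rescaled TPM and those of microRNA in what the authors called TPM. Read depth is unknown for both.

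The targeted genes were examined in every mRNA library. Psmc3ip was 3.51 and 5.06 in the Hop2 KO libraries, against 22.8 and 26.4 in Prdm9 KO and 197 in wild type, so its low values matched the Hop2 labels. Prdm9 was 4.73 and 5.93 in Prdm9 KO, 10.7 and 15.0 in Hop2 KO and 6.20 in wild type. The Prdm9 KO values were below Hop2 KO by 1.12 on the log2 scale (-1.12, SE 0.21, limma unadjusted p = 0.00369, Benjamini-Hochberg adjusted p = 0.972) and close to wild type, and the deleted exons are not given in the sources used here, so the gene value checks the Prdm9 label only weakly. Morc2b, reported in earlier work to depend on PRDM9, was 1.04 and 1.84 in Prdm9 KO, 0.286 and 0.477 in Hop2 KO and 164 in wild type, so it was low in both knockouts.

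**Figure D1:**
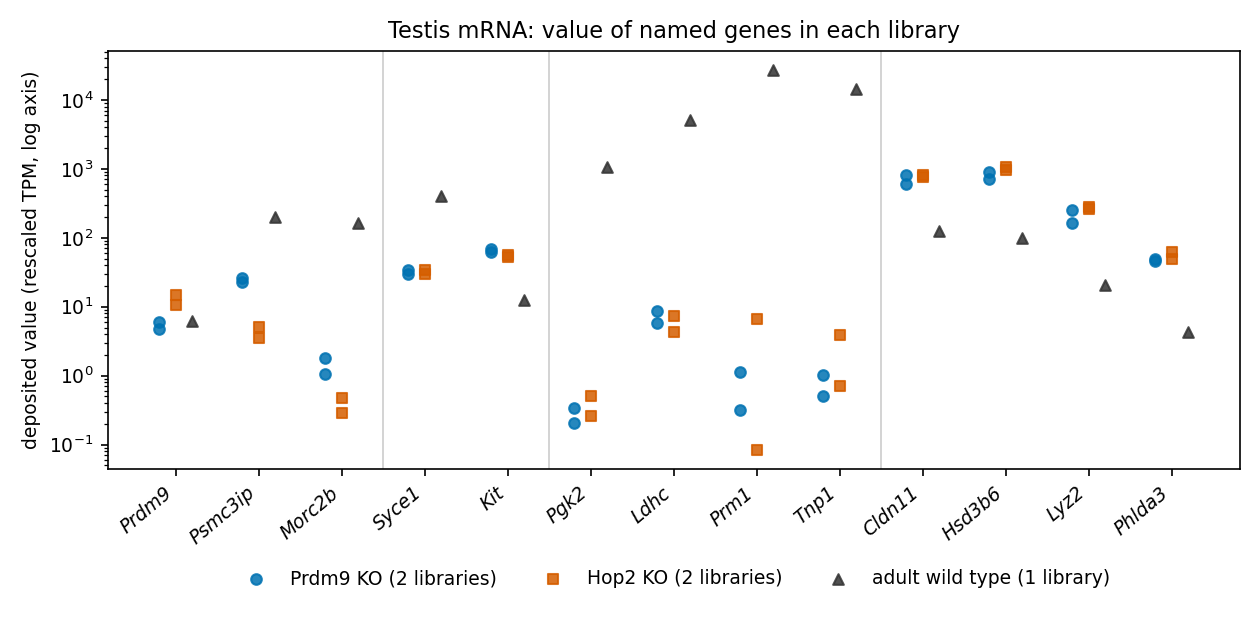
Deposited value (rescaled TPM, log axis) of 13 named genes in each mRNA library: circles, 2 Prdm9 KO; squares, 2 Hop2 KO; triangle, 1 adult wild type. The groups from left to right are targeted genes and Morc2b, an early meiotic and a spermatogonial gene, genes of pachytene and spermatids, and Sertoli, Leydig, macrophage and p53 target genes; Prm1 was 27280 in wild type and at most 6.55 in a knockout.

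Prdm9 KO and Hop2 KO testes were compared because spermatocytes of both mutants stop in meiotic prophase, so that differences would go beyond a shared arrest. Such differences cannot tell loss of PRDM9 from loss of HOP2. Few genes passed between them. Of 14358 genes tested, 2 rose in Prdm9 KO and 0 fell (limma, Benjamini-Hochberg), and 445 had an unadjusted p under 0.05. The authors' deposited table lists 1 gene with q under 0.05 and 835 of 21276 listed genes with p under 0.05. Of the 835, 370 were also under 0.05 in limma, which tested fewer genes after its filter. In limma and in that table the share of genes with p under 0.05 was below the 0.05 that chance gives. Across genes, replicates correlated at 0.9834 (Prdm9 KO) and 0.9821 (Hop2 KO). Same-numbered libraries of different genotype correlated at 0.9888 and 0.9845, and differently numbered ones at 0.982 and 0.9773. With same-numbered libraries taken as pairs, which the labels do not give, 1536 genes had an unadjusted p under 0.05. The low share therefore does not show that the knockouts are alike. Both genes that rose are pseudogenes, named here after their values were seen, and their values are uncertain because reads of near-identical copies can be shared. Gm13456 (chromosome 2, start 40555685, GRCm38.p6) was 69.0 ± 0.780 (SD, n = 2) in Prdm9 KO and 1.60 ± 0.328 (n = 2) in Hop2 KO, a log2 change of 4.76 (SE 0.14, limma adjusted p = 0.0108), and its q was 0.0302 in the authors' deposited table. Gm9825 (chromosome 6, start 7981814) was 83.2 ± 27.5 and 0.245 ± 0.131 (log2 6.05, SE 0.26, limma adjusted p = 0.0289). Groups did not overlap for 32.9% of genes, where chance gives 33.3%.

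Neither call held in every fit. Without the filter, and with all 5 libraries in the fit, limma made 0 calls (980 and 647 genes at an unadjusted p under 0.05), and with a pseudocount of 5 it kept Gm13456 only. Without Prdm9 KO replicate 1, Gm13456 and Gm9825 had adjusted p = 0.0553 and 0.0513 and 3 other genes passed. Without Prdm9 KO replicate 2, 10 genes passed. Gm9825 also lost its call without Hop2 KO replicate 1 (0.0666; 2 genes higher and 2 lower) and replicate 2 (0.0545).

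Among other genes, 5 per direction are named by smallest unadjusted p, and limma called none of them. Besides Psmc3ip (log2 2.29, SE 0.19, adjusted p = 0.205), the higher values in Prdm9 KO belonged to Myom3, a muscle M-band protein (9.35 against 2.26), Dnah8, a sperm axonemal dynein (3.66 against 0.748), the T cell receptor joining segment Trbj2-3 (1.77 and 2.42, listed at 0 in both Hop2 KO libraries) and BTF3L4 (4.41 against 1.38). The lower values belonged to the histone H4 gene Hist1h4m, which has near-identical copies (8.39e-06 and listed at 0, against 2.99 and 3.17), Trbj2-1 (listed at 0 in both Prdm9 KO libraries, 2.29 and 2.56 in Hop2 KO), Cypt1, expressed in spermatids (2.19 against 6.80), Sh3bgr (3.66 against 8.63) and Id3, an inhibitor of helix-loop-helix transcription factors (17.5 against 28.3).

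Of the gene lists, spermatogonial and DNA repair genes were higher as sets in Prdm9 KO than in Hop2 KO, by small amounts. Of 24 spermatogonial genes 16 had a positive log2 change (median 0.10, camera adjusted p = 0.0355; adjusted p = 0.758 with an estimated correlation). Gfra1, a receptor of undifferentiated spermatogonia (log2 0.52), Nanos3 (0.30), Sall4 (0.27) and Kit, of differentiating spermatogonia (0.26), had the largest values. Of 30 DNA repair genes 22 were positive (median 0.07, camera adjusted p = 0.0398; adjusted p = 0.758 with an estimated correlation), with Mdc1 at 0.41, Xrcc2 at 0.40, Topbp1 at 0.21 and Rpa3 at -0.23. Sertoli genes were negative in 17 of 20 (median -0.18, adjusted p = 0.243). The spermatogonial call was lost without Prdm9 KO replicate 1 (0.0524), Prdm9 KO replicate 2 (0.0698) or Hop2 KO replicate 2 (0.371), with no filter (0.102) and with a minimum mean of 5 (0.153). The DNA repair call was lost without Prdm9 KO replicate 2 (0.301), Hop2 KO replicate 1 (0.276) or Hop2 KO replicate 2 (0.0553), with no filter (0.136), a minimum mean of 5 (0.0649) or quantile normalization (0.0825).

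The other lists did not pass between the 2 knockouts in the unpaired fit, with the values as deposited and the filter of the plan. With same-numbered libraries taken as pairs, which the labels do not give, 5 lists passed in all. H3K4 methylation genes came closest (15 of 22 positive, adjusted p = 0.0682, Kmt2a at 0.41), followed by spermatid genes (11 of 13 negative, 0.243), myoid genes (9 of 10 negative, 0.243), cell cycle genes (11 of 18 positive, 0.243), macrophage genes (13 of 18 negative, 0.250) and pachytene genes (14 of 21 positive, 0.266, Piwil1 at 0.45). Leydig, endothelial and p53 lists and the piRNA list had an adjusted p of 0.402, red blood cell genes 0.422, early meiotic genes 0.463 (Ankrd31 at 0.35) and Y-linked genes 0.582. The medians of the early meiotic, p53 and piRNA lists were slightly negative (-0.03, -0.00326 and -0.00236) where camera pointed up. In no list of at least 5 genes did a member pass when adjusted over the list alone (0 members), and of the targeted genes Psmc3ip and Prdm9 did. Of 2 tested epididymal genes neither passed. H3K4 methylation genes passed with median-ratio scaling (0.0389), quantile normalization (0.0253) and rescaled columns (0.0212), and spermatid genes, lower, with no filter (0.0278). Leaving out 1 library made several of these lists pass. Without Prdm9 KO replicate 1 these were H3K4 methylation (0.0133), Sertoli (0.0136, Aard at -0.34 and Inha at -0.32 with all libraries), macrophage (0.000145), myoid (0.00481), pachytene (0.00109) and red blood cell genes (0.00704, lower). Without Prdm9 KO replicate 2 red blood cell genes (1.46e-07, higher) and spermatid genes (0.0205) passed, without Hop2 KO replicate 1 spermatid (3.85e-06) and cell cycle genes (0.0347), and without Hop2 KO replicate 2 macrophage and myoid genes (0.0271 each).

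Prdm9 KO testis was compared with adult wild-type testis to describe the arrested tissue. Transcripts of spermatids and of late spermatocytes were nearly gone, and markers of Sertoli cells, Leydig cells, macrophages and spermatogonia were higher. Of 16261 genes tested, 5631 rose and 6412 fell (limma, adjusted p under 0.05 after Benjamini-Hochberg adjustment), with the single wild-type library assumed to vary like the knockouts. The share of higher calls, 46.8%, was 61.8% after quantile normalization and 66.0% with columns rescaled to 1000000, as the median log2 change over all genes moved from -0.08 to 0.58 and 0.77. The lists named below as changed kept their direction in every scaling.

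All 39 spermatid genes fell (median log2 -9.37). The protamine genes Prm1 and Prm2, which package sperm DNA, had log2 changes of -13.99 (SE 1.32) and -14.59 (SE 1.62), the transition protein genes Tnp1 and Tnp2 -13.01 and -14.17, and Smcp, of the sperm mitochondrial capsule, -12.59. Prm1 was 27280 in wild type and 0.313 and 1.15 in Prdm9 KO. Of 30 genes switched on at pachytene, 29 fell (median -5.73), among them Adam3, needed for sperm to reach the egg (-10.07), Pgk2, the glycolytic kinase of the male germ line (-9.73), and Ldhc, the germ cell lactate dehydrogenase (-9.27). Of 20 piRNA pathway genes 14 fell and 2 rose (median -2.03), with Gtsf1 at -5.0, Tdrd5 at -3.16 and Ddx4 at -3.01. Camera gave adjusted p = 2.13e-11 for spermatid, 2.02e-07 for pachytene and 0.0397 for piRNA genes; adjusted p = 0.534 with an estimated correlation for each. Adjusted over the list alone, 39, 30 and 14 members fell and 3 piRNA genes rose, and the piRNA call was lost without Prdm9 KO replicate 1 (0.0537) and without the filter (0.138).

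Early meiotic prophase genes went both ways, with 11 of 38 higher, 13 lower and no set call (camera adjusted p = 0.974, pointing up although the median was -0.10); the counts were 11 and 13 when adjusted over the list alone. Mael (-3.62) and the synaptonemal complex gene Syce1 (-3.60) fell most. Named after their values were seen, Dmc1, the meiotic recombinase, rose by 1.71 and Stra8, which switches on meiosis, by 1.99, while Spo11, whose product makes the breaks, fell by 2.59. Of 24 spermatogonial genes 18 rose and 3 fell, also when adjusted over the list alone (median 1.38, camera adjusted p = 0.00253; adjusted p = 0.534 with an estimated correlation), including Rhox13 (2.45), Kit (2.30) and Crabp1 (2.02).

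Somatic markers rose, by amounts that differed between cell types. All 18 macrophage genes rose (median 2.47), with Lyz2 at 3.25, C1qa at 3.10 and Csf1r, the receptor of a macrophage growth factor, at 2.96. Of 20 Sertoli genes 16 rose (median 2.04), among them Trf (2.64), Defb36 (2.55) and the tight junction gene Cldn11 (2.45). Of 15 Leydig genes 12 rose (median 2.31), with the steroid enzyme gene Hsd3b6 at 3.01 and the luteinizing hormone receptor gene Lhcgr at 2.78. Insl3, a Leydig hormone of very high value (31180 and 44710 against 5124), did not pass (2.87, SE 2.19, limma adjusted p = 0.300) but did with quantile normalization (0.00161) or without the trend (0.0452). Endothelial (6 of 10 higher, 1 lower, median 0.80, Robo4 at 3.77) and myoid genes (5 of 10 higher, 1 lower, median 1.05, Myl9 at 1.94) passed closely, and Actg2, a smooth muscle actin of the myoid list, fell by 6.66. Camera gave adjusted p = 2.14e-05 for Sertoli, 0.000124 for Leydig, 6.5e-05 for macrophage and 0.0453 for both endothelial and myoid genes; adjusted p = 0.534 with an estimated correlation for all of these but myoid genes (adjusted p = 0.698 with an estimated correlation). Adjusted over the list alone, 18 Sertoli, 12 Leydig, 18 macrophage, 6 endothelial and 5 myoid genes rose. The endothelial call was lost without Prdm9 KO replicate 1 (0.0609), and the myoid call without Prdm9 KO replicate 1 (0.0622), Hop2 KO replicate 1 (0.0519) or Hop2 KO replicate 2 (0.0517).

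Of 17 p53 target and apoptosis genes 12 rose and 3 fell, also when adjusted over the list alone (median 1.5, camera adjusted p = 0.0145; adjusted p = 0.534 with an estimated correlation), with Phlda3 at 3.17, Ccng1 at 2.5 and the death receptor gene Fas at 2.09. Of 8 Y-linked genes 5 rose, and 2 when adjusted over the list alone (median 1.00, adjusted p = 0.0397; adjusted p = 0.534 with an estimated correlation), with Ddx3y at 1.65. The p53, Y-linked, endothelial and myoid calls were lost with quantile normalization (0.0624, 0.0724, 0.0780 and 0.112) and with rescaled columns (0.0832, 0.107, 0.0832 and 0.156). Y-linked, endothelial and myoid calls were also lost with a minimum mean of 5 (0.0623, 0.358 and 0.105), and the last 2 with a pseudocount of 5 (0.0573 and 0.0507). DNA repair (4 higher and 9 lower of 30, adjusted p = 0.636, Rpa1 at -2.22), cell cycle (5 and 8 of 18, 0.620, Foxm1 at -3.25), H3K4 methylation (7 and 11 of 22, 0.620, Cdyl at -3.33) and red blood cell genes (1 and 0 of 5, 0.409, Hbb-bs at 1.43) did not pass, although red blood cell genes did without Prdm9 KO replicate 2 (0.0495). Adjusted over the list alone these counts were 3 and 7, 5 and 8, 7 and 11, and 0. Hbb-bs lost its call without Prdm9 KO replicate 1 (0.0516), Hop2 KO replicate 1 (0.0982) or Hop2 KO replicate 2 (0.0992). Of 2 epididymal genes 1 fell. Among all genes past the threshold the largest rises included Serpina3n, an inhibitor of serine proteases (5.68, SE 0.35), Timp1, an inhibitor of metalloproteinases (5.41, SE 0.32), and Igfbp3 (4.90, SE 0.11). Psmc3ip fell by 2.96, and Morc2b fell by 6.10. Prdm9 itself had a log2 change of -0.19 (limma adjusted p = 0.567), which turned to 0.39 with quantile normalization and 0.59 with rescaled columns.

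Hop2 KO testis, compared with the same wild-type library, showed loss of spermatid and late spermatocyte transcripts and higher somatic and spermatogonial markers as well. Part of any resemblance to the Prdm9 KO comparison comes from the shared wild-type library. Of 16261 genes, 5691 rose and 6419 fell (limma, Benjamini-Hochberg), and the share of higher calls, 47.0%, was 61.5% after quantile normalization and 64.0% with rescaled columns (median log2 change -0.06, then 0.59 and 0.68). All 39 spermatid genes fell (median -9.40), with Prm2 at -13.48, Prm1 at -13.22, Tnp2 at -13.19, Tnp1 at -12.28 and Smcp at -11.95. Prm1 was 0.0842 and 6.55, and Hop2 KO replicate 2 had the highest sum of spermatid transcripts of the 4 knockout libraries (0.0937% of wild type, against 0.0594% to 0.0710%). Of 30 pachytene genes 29 fell (median -5.78), with Adam3 at -9.87, Pgk2 at -9.61 and Ldhc at -9.56, and of 20 piRNA genes 14 fell and 2 rose (median -2.09), with Gtsf1 at -4.92, Tdrd5 at -3.17 and Ddx4 at -2.97. Camera gave adjusted p = 2.31e-11, 1.76e-07 and 0.0328; adjusted p = 0.505 with an estimated correlation for each. Adjusted over the list alone, 39, 30 and 14 members fell and 3 piRNA genes rose, and the piRNA call was lost without the filter (0.0988).

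Early meiotic genes again went both ways in Hop2 KO (11 of 38 higher and 14 lower, also when adjusted over the list alone, camera adjusted p = 0.948), with Syce1 at -3.60, Mael at -3.57, Spo11 at -2.41, Stra8 at 2.09 and Dmc1 at 1.81, the last 3 named after their values were seen. Spermatogonial genes rose in 18 and fell in 4 of 24, also when adjusted over the list alone (median 1.24, adjusted p = 0.00636; adjusted p = 0.505 with an estimated correlation), with Rhox13 at 2.5, Crabp1 at 2.06 and Kit at 2.04. Of Sertoli genes 17 of 20 rose (median 2.17, Defb36 at 2.84, Trf at 2.84, Inha at 2.67), of Leydig genes 12 of 15 (median 2.51, Hsd3b6 at 3.34, Hsd17b3 at 2.91), of macrophage genes 17 of 18 (median 2.46, Lyz2 at 3.65, C1qa at 3.52), of endothelial genes 7 of 10 (median 1.02, Robo4 at 3.72) and of myoid genes 7 of 10 with 1 lower (median 1.16, Myl9 at 2.15, Actg2 at -6.53). Camera gave adjusted p = 2.22e-05, 0.000107, 6.3e-05, 0.0345 and 0.0345 in that order; adjusted p = 0.505 with an estimated correlation for these, except myoid genes (adjusted p = 0.606 with an estimated correlation). Adjusted over the list alone 19, 14, 18, 7 and 7 rose. Insl3 did not pass (21030 and 68220 against 5124, 2.89, limma adjusted p = 0.298), except with quantile normalization (0.00160) or without the trend (0.0441). The myoid call was lost without Hop2 KO replicate 1 (0.0576).

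Of 17 p53 targets 12 rose and 3 fell in Hop2 KO, also over the list alone (median 1.45, adjusted p = 0.0259; adjusted p = 0.505 with an estimated correlation), with Phlda3 at 3.39, Ccng1 at 2.53 and Fas at 2.30. Of 8 Y-linked genes 5 rose, also over the list alone (median 1.08, adjusted p = 0.0345; adjusted p = 0.505 with an estimated correlation), with Ddx3y at 1.63. The p53, Y-linked, endothelial and myoid calls were lost with quantile normalization (0.0651, 0.0651, 0.0651 and 0.0855) and rescaled columns (0.0796, 0.101, 0.0705 and 0.110), and the last 3 also with a minimum mean of 5 (0.0664, 0.308 and 0.0740). DNA repair (4 higher and 9 lower of 30, adjusted p = 0.431, Rpa1 at -2.26), cell cycle (6 and 8 of 18, 0.510, Foxm1 at -3.54), H3K4 methylation (4 and 11 of 22, 0.463, Cdyl at -3.31) and red blood cell genes (0 of 5, 0.431) did not pass. Of 2 epididymal genes 1 fell. Timp1 (5.79, SE 0.32), Serpina3n (5.74, SE 0.35) and Igfbp3 (4.76, SE 0.11) were among the largest rises. Psmc3ip fell by 5.25 (SE 0.24), and Morc2b fell by 6.91 (SE 0.26). Prdm9 was higher by 0.93 (SE 0.28, limma adjusted p = 0.0464), a call lost without Prdm9 KO replicate 1 (0.0865), Prdm9 KO replicate 2 (0.0867) or Hop2 KO replicate 2 (0.0900), without the filter (0.0805) and with median-ratio scaling (0.0539).

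MicroRNAs of Prdm9 KO and Hop2 KO testis were compared in 4 libraries, and no single microRNA passed. Of 339 tested, 0 passed in limma, 14 had an unadjusted p under 0.05 and the smallest Benjamini-Hochberg adjusted p was 0.157. Limma took the spread of each microRNA wholly from the trend over all 339 (678 degrees of freedom). Its SEs and p-values therefore leave out the replicate spread of the single microRNA. The authors' deposited table has 0 adjusted p under 0.05, 69 of 2070 lines with p under 0.05 and a smallest adjusted p of 0.0775, for miR-135a-5p. In limma mmu-miR-135a-5p also came closest, at 39.3 and 60.1 in Prdm9 KO against 9.94 and 11.3 in Hop2 KO (log2 2.1, SE 0.60), and it passed without the trend (0.0385). The next by p within each direction were mmu-miR-99a-5p (1.34), mmu-miR-20a-5p (1.21), mmu-miR-200c-3p (1.59) and mmu-miR-503-5p (1.23), higher in Prdm9 KO, and mmu-miR-148a-3p (-1.13), mmu-miR-744-5p (-1.19), mmu-miR-379-5p (-1.06) and mmu-let-7f-5p (-0.84), lower. Hop2 KO replicate 2 stood apart from the rest, with a correlation across microRNAs of 0.962 to 0.969 with the other libraries and 64.6% of its total in 10 microRNAs (53.8% to 57.9% elsewhere). With it as the only Hop2 KO library, 14 microRNAs were higher and 2 lower, while without it mmu-miR-99a-5p turned to -0.19 (2.87 without Hop2 KO replicate 1). Other values also rested on single libraries: mmu-miR-200c-3p was 2.70 without Prdm9 KO replicate 1 and 0.48 without replicate 2, and mmu-miR-148a-3p -0.47 and -1.78. mmu-miR-503-5p was 1.87 without Hop2 KO replicate 1 and 0.59 without replicate 2.

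Of the microRNA lists, 4 passed with the preset correlation and none (0) with an estimated one. The miR-17-92 and related clusters, which promote proliferation, were higher in Prdm9 KO (12 of 14 positive, median 0.74, camera adjusted p = 0.00168; adjusted p = 0.721 with an estimated correlation), with mmu-miR-20a-5p at 1.21 and mmu-miR-17-5p at 1.00. X-linked germ cell microRNAs were also higher (26 of 33 positive, median 0.50, adjusted p = 0.0108; adjusted p = 0.721 with an estimated correlation), with mmu-miR-465d-3p at 1.08 and mmu-miR-883b-3p at 0.93. The let-7 family, which marks differentiation, was lower (11 of 15 negative, median -0.32, adjusted p = 0.000966; adjusted p = 0.420 with an estimated correlation), with mmu-let-7f-5p at -0.84 and mmu-let-7d-5p at -0.73. Imprinted Dlk1-Dio3 microRNAs were lower (13 of 20 negative, median -0.11, adjusted p = 0.00658; adjusted p = 0.420 with an estimated correlation), with mmu-miR-379-5p at -1.06 and mmu-miR-370-3p at -0.80. Some members are not independent: mmu-miR-465a-3p and mmu-miR-465b-3p have the same values in every library, as do mmu-let-7a-1-3p and mmu-let-7c-2-3p. With names of like values counted once, the X-linked list had adjusted p = 0.0272 and the let-7 list 0.00162 in camera, and the 4 lists passed. All 4 calls were lost without Prdm9 KO replicate 1 (0.430, 0.297, 0.113 and 0.195). The median log2 change over all microRNAs was 0.17 and became -0.03 with median-ratio scaling, under which the 4 lists still passed. The immune list (6 of 7 positive, adjusted p = 0.0649, mmu-miR-142a-3p at 1.02) passed without Hop2 KO replicate 1 (0.0218) and with a minimum mean of 100 (0.0343). Without Hop2 KO replicate 1 and 2 in turn, mmu-miR-142a-3p was 1.94 and 0.11, and mmu-miR-144-3p 1.59 and 0.12. Red blood cell (0.158, mmu-miR-144-3p at 0.85), muscle (0.598, pointing down although the median was 0.29, mmu-miR-145a-5p at 0.70), miR-34 and miR-449 (0.955, mmu-miR-34c-5p at 0.15, -0.06 with median-ratio scaling) and miR-29, miR-30 and miR-200 microRNAs (0.955, pointing down although the median was 0.18) did not pass. No member of any list passed when adjusted over the list alone (0 members). The miR-290 list had 1 tested member (-0.23) and the endothelial and Sertoli lists 2 each (medians 0.59 and 0.27).

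Breaks in Prdm9 K/K testis were mapped to ask where they form when PRDM9 lacks its KRAB domain. The listed peaks lay at gene ends far more often than chance placed them. The authors list 17731 peaks, with a median width of 1849 bp and 35.2 Mb in all, 1.29% of the chromosomes. Of 9397213 fragment lines 26.4% lay in peaks (exact binomial 95% interval 26.36% to 26.41%), and distinct fragments were 27.3 times as dense inside peaks as outside. The peaks come from this same library, so a higher density inside them follows from the way peaks are called. Of the peaks, 9009 (50.8%, interval 50.07% to 51.55%) lay within 1000 bp of either end of a protein-coding gene, against a mean of 5.81% and a maximum of 6.35% over 1000 random placements (one-sided permutation p = 0.001, the smallest they can give). Away from gene ends, 43.6% of the remaining 8722 peaks lay inside genes, against 41.6% of placements. These placements could also fall at gene ends, from which the 8722 peaks are barred, so the shares are not alike and decide nothing.

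Fragments around the middles of peaks had the strand pattern of resected break ends. On the left of the middle 80.1% were on the plus strand and on the right 19.7%, while outside peaks 50.4% were on the minus strand. At gene ends the plus strand made up 80.5% on the left and 19.2% on the right, and away from gene ends 79.5% and 20.7%.

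**Figure D2:**
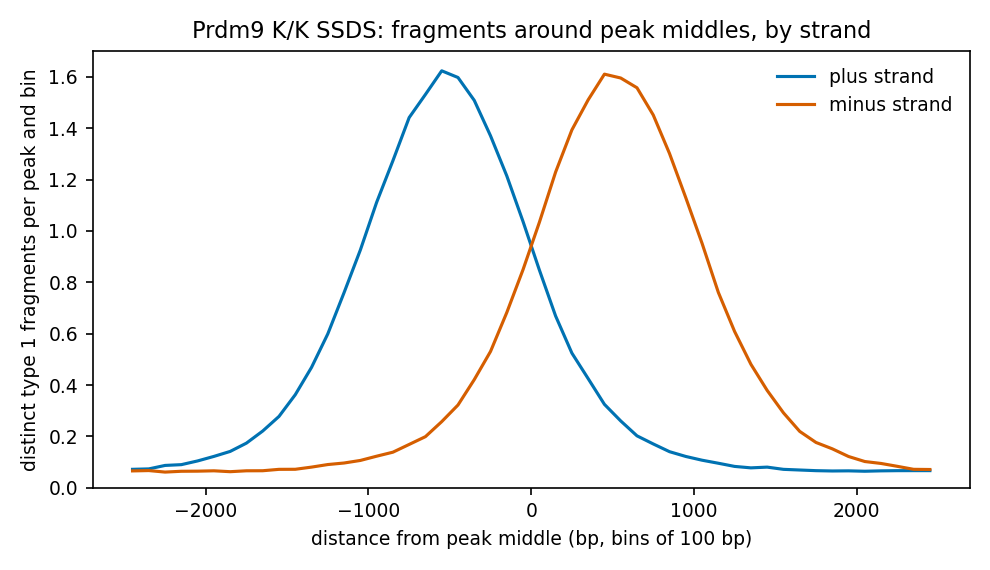
Distinct type 1 fragments per peak and bin of 100 bp against the distance from the peak middle (bp), for the plus and the minus strand, averaged over 17731 peaks of the 1 Prdm9 K/K library. The plus strand is highest left of the middle (1.62 at -550 bp) and the minus strand right of it (1.61 at 450 bp).

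Stronger peaks lay at annotated gene ends more often, but the 5 with most fragments did not. Ranked by distinct fragments in 10 equal groups, the share at gene ends was 32.5% in the weakest and 81.4% in the strongest group. The 5 peaks with most fragments all lay inside genes away from their ends: Plekha5 on chromosome 6 (140588386 to 140594537, 1234 fragments), Enpp6 on chromosome 8 (47000931 to 47006866, 894), Nrg1, a growth factor gene, on chromosome 8 (32247708 to 32251977, 862), Rsbn1l with the noncoding A630072M18Rik on chromosome 5 (20949574 to 20953129, 510) and the mucin gene Muc3 on chromosome 5 (137152183 to 137155168, 497). Of the top 10 peaks 3 lay at gene ends, and of the top 100, 74. Only the outermost ends of protein-coding genes were counted. A start site inside a gene or an end of a noncoding gene would be missed. Among the genes with most fragments in a peak at an end were Rims2 (472), Fndc3a (470), Acbd5 (444) and Igf2bp3 (443). Coordinates are those of the files (mm10), with starts counted from 1.

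The X chromosome held fewer peaks than autosomes, with more fragments in each. It had 3.57 peaks per Mb against 6.96 on autosomes, a ratio of 0.513, and 0.667 for the stronger 8882 peaks. Single autosomes ranged from 5.72 to 10.3. The median peak on X held 31 distinct fragments, against 22. Distinct fragments in peaks per Mb had a ratio of 0.678, and those outside peaks 0.543. Male cells carry a single X and paired autosomes, and these densities were not adjusted for copy number, so they do not show fewer breaks per X copy. The Y held 1 peak, at the histone demethylase gene Uty (19 fragments), and 86.0% of its 29877 fragments had mapping quality 0 in both reads, against 5.75% of all fragments, so breaks on the Y could not be judged at this mappability.

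Genes expressed in Prdm9 KO testis carried K/K peaks at their ends more often than silent ones. Of 1828 protein-coding genes listed at 0 in both Prdm9 KO libraries 1.37% had a peak (interval 0.887% to 2.01%). Of the remainder, cut into 10 equal groups by mean value, the share rose from 8.90% in the lowest to 74.2% in group 8 and was 68.6% in the highest. Early meiotic (35 of 37), DNA repair (27 of 29), cell cycle (16 of 18) and H3K4 methylation genes (19 of 22) mostly had a peak. Spermatid (10 of 38), Sertoli (5 of 20), Leydig (3 of 15) and macrophage genes (4 of 18) mostly did not. Of all 20597 matched protein-coding genes, 9583 had one. The shares of the lists were not adjusted for expression. Prdm9 (39 fragments), Psmc3ip (8) and Hormad1 (26), an axis protein gene, had a peak at an end, and Morc2b and Spo11 had none (0 fragments in a peak). As a set, the 8454 tested genes with a peak did not pass against the other 4454 for their change between Prdm9 KO and Hop2 KO (medians -0.03 and -0.05, adjusted p = 0.493 in limma's camera, in a family of 1 test).

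**Figure D3:**
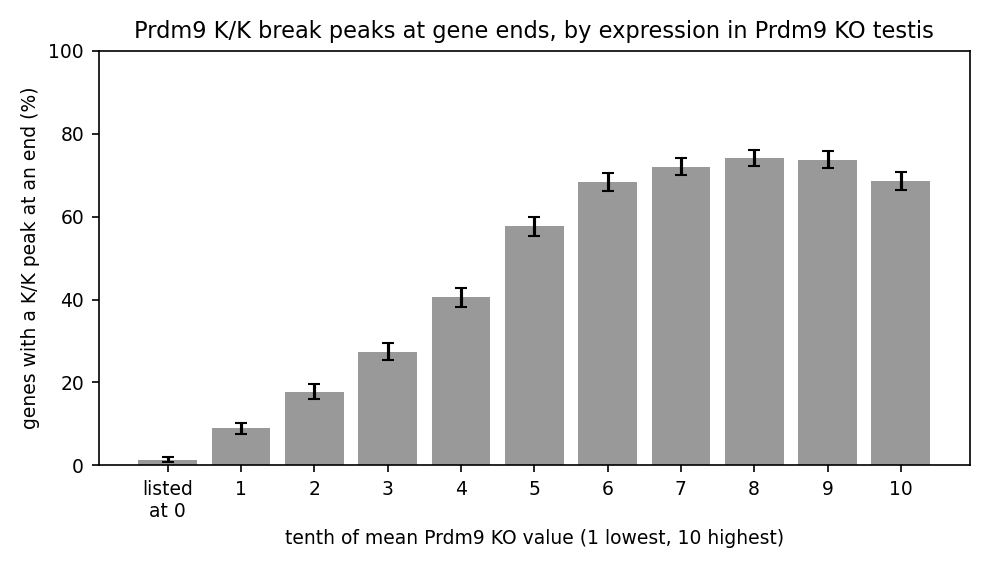
Percent of protein-coding genes with a Prdm9 K/K peak within 1000 bp of either end, for genes listed at 0 in Prdm9 KO testis and for 10 equal groups of rising mean value. Bars are shares and error bars exact binomial 95% intervals; the share is 1.37% at 0, 8.90% in the lowest group and 68.6% in the highest.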

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

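The transcripts and the end of the X chromosome described here were examined after the comparisons of the report had been seen, and no test was made on them. The transcript table was not used in the comparisons. In it the Prdm9 transcript ENSMUST00000132675 was 1.65 in each of the 2 Prdm9 KO libraries, above 0.244 and 0.360 in Hop2 KO and 0.555 in wild type, although the gene as a whole was lower in Prdm9 KO than in Hop2 KO. The Psmc3ip transcript ENSMUST00000134520 was 1.35 and 1.29 in the 2 Hop2 KO libraries, above 0.0420 and 0.106 in Prdm9 KO and 0.274 in wild type, while the other listed Psmc3ip transcripts were lower in Hop2 KO. ENSMUST00000126386, the Psmc3ip transcript with the highest wild-type value (112), was 1.25 in Hop2 KO replicate 1 and listed at 0 in replicate 2. The position of these transcripts relative to the deleted exons is not given in the sources used here.

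In the break map, 4223 distinct fragments lay past the last peak of the X chromosome, which ends at 169465185. This stretch of 1.42 Mb held 2980 distinct fragments per Mb, against 593 over the whole X, and no peak was listed in it.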

How the results depend on the processing

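Rescaling of the mRNA columns to 1000000, the peaks and placements ranked by or drawn at fragments, the ends of all annotated genes, the set test against all genes tested and the counting of microRNA names of like values once were chosen after seeing the data. Leaving out a library leaves a group with 1 library, assumed to vary like the others. Peaks of higher score were not run, since the list holds no score, and a count model of the microRNAs was planned only for whole counts. Read depth of the mRNA and microRNA libraries is unknown, so counting error could not be set against the spread. The cause of a change was not tested except where the setting removes genes or libraries.

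Between Prdm9 KO and Hop2 KO mRNA, limma called 1 gene higher with a pseudocount of 5, 0 with no filter (980 genes at an unadjusted p under 0.05), 0 with all 5 libraries in 1 fit (647) and 2 to 10 with 1 library left out, where 0 to 2 were lower. Of the 2 calls, 0 were kept without Prdm9 KO replicate 1, and the 10 came without Prdm9 KO replicate 2. Against wild type the lower calls numbered 12045 with no filter and 4269 with rescaled columns in Prdm9 KO, and 12121 with no filter in Hop2 KO, where no filter means that more genes were tested. For microRNAs limma called 1 higher without the trend, and 0 to 14 higher and 0 to 2 lower with 1 library left out, the most without Hop2 KO replicate 1.

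Same-numbered libraries were not taken as pairs: the deviations from group means correlated at 0.413 (mRNA) and 0.0494 (microRNA) over 2 pairs, and the labels name no shared animal. With the replicate block limma called 8 genes higher between the knockouts (1536 at an unadjusted p under 0.05) and 1 microRNA higher, and 5 mRNA lists passed.

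Lists past an adjusted p of 0.05 between the knockouts numbered 1 with no filter, 3 with median-ratio scaling or rescaled columns, 0 with a minimum mean of 5 and 0 with an estimated correlation, and 2 to 7 with 1 library left out. Against wild type 7 passed in each knockout with quantile normalization and 7 with rescaled columns, 8 in each with a minimum mean of 5, 9 in Prdm9 KO with a pseudocount of 5, and 0 with an estimated correlation. Of the microRNA lists 0 passed with an estimated correlation and 0 to 5 with 1 library left out. With names within 1% of an earlier one in every library counted once (9 names left out of 339), 0 microRNAs and 4 lists passed.

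Some lists that had not passed turned direction, still without passing. Between the knockouts this held with no filter for early meiotic (adjusted p = 0.976), pachytene (0.894) and Y-linked genes (0.976), and with quantile normalization for Leydig genes (0.792). In Prdm9 KO against wild type it held with no filter for cell cycle (0.947), DNA repair (0.900) and H3K4 methylation genes (0.947), with quantile normalization for DNA repair, early meiotic and H3K4 methylation genes (0.984 each), with rescaled columns for DNA repair genes (0.617), and for early meiotic genes with a pseudocount of 0.1 (0.924) and a minimum mean of 5 (0.869). In Hop2 KO against wild type it held for DNA repair genes with rescaled columns (0.890) and early meiotic genes with no filter (0.483). Among microRNAs the miR-29, miR-30 and miR-200 list (0.483) and the muscle list (0.384) turned with no filter.

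With 1 library left out, other lists turned in at least 1 case. Between the knockouts the adjusted p ranged from 1.46e-07 to 0.999 for red blood cell, 0.0347 to 0.769 for cell cycle, 0.182 to 0.891 for early meiotic, 0.0917 to 0.999 for endothelial, 0.000145 to 0.999 for macrophage, 0.00109 to 0.999 for pachytene, 0.00481 to 0.999 for myoid, 0.126 to 0.985 for piRNA, 3.85e-06 to 0.810 for spermatid and 0.0586 to 0.876 for Y-linked genes. For early meiotic genes it ranged from 0.890 to 0.953 in Prdm9 KO and from 0.795 to 0.935 in Hop2 KO against wild type. Among microRNAs it ranged from 0.0218 to 0.954 for the immune list, 0.560 to 0.804 for miR-29, miR-30 and miR-200 and 0.377 to 0.714 for miR-34 and miR-449.

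Of single genes and microRNAs, Prdm9 in Prdm9 KO against wild type had a log2 change of 0.39 with quantile normalization and 0.59 with rescaled columns. mmu-miR-34c-5p was -0.0643 with median-ratio scaling and ranged from -0.26 to 0.56 with 1 library left out, and mmu-miR-99a-5p from -0.19 to 2.87. Over the named genes and microRNAs, 1072 values in other settings kept direction and side of the threshold, 10 lost and 7 gained a call, and with 1 library left out 510 kept, 10 lost and 6 gained. Over single lists 459 kept, 59 lost and 8 gained, and with 1 library left out 178 kept, 16 lost and 13 gained.

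In the break map the share of fragments in peaks was 26.33% for distinct fragments and 22.15% in the stronger 8882 peaks, and the ratio of peak density on X to autosomes was 0.667 in these. Peaks at gene ends made up 48.8% with a window of 500 bp (placements 4.47%), 54.7% with 2500 bp (9.50%), 45.7% by the peak middle (3.11%), 65.1% in the stronger peaks (6.46%) and 60.6% at ends of all annotated genes (11.4%). The camera p of genes with a peak ranged from 0.486 to 0.827 over the settings of limma.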

Other observations

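The tests of genes near the targeted loci, of near-identical copies, of the spread between somatic lists, of scaling and of placements at fragments were chosen after the results were seen, and the strand test at gene ends was chosen when the split over all peaks was known. Chromosome 19 had the most peaks per Mb in Prdm9 K/K testis (10.3) and chromosome 1 the fewest of the autosomes (5.72). Of the lists not given in the report, a peak at an end was found for 19 of 29 pachytene genes, 15 of 24 spermatogonial genes, 13 of 20 piRNA pathway genes, 10 of 17 p53 targets, 5 of 10 myoid genes, 3 of 10 endothelial genes, 1 of 8 Y-linked genes and 0 of 5 red blood cell and 0 of 2 epididymal genes. These are values, and lists were not tested against each other.

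Between Prdm9 KO and Hop2 KO, 17 genes had an unadjusted p under 0.001 in limma, of which 15 were higher in Prdm9 KO. Several ribosomal and other pseudogenes, chosen here after their values were seen, were high in Prdm9 KO and near 0 in Hop2 KO: Rpl38-ps2 (74.3 and 156, listed at 0 in both Hop2 KO libraries, 55.5 in wild type), Rps2-ps10 (285 and 108 against 1.56 and 0.185) and Gm15487 (599 and 253 against 2.69 and 0.468). Of 16 placed genes, 6 lay on chromosome 6, where random draws of genes had a median of 3 and a 95th percentile of 4 on their most crowded chromosome (share 0.0041 of 10000 draws), which was noticed before it was computed. These 6 include Trbj2-1 (start 41542754) and Trbj2-3 (start 41543223), neighbouring segments that changed in opposite directions. The draws count them as independent, so the share overstates the crowding.

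A candidate explanation of these small p-values is sequence that differs between the strains in which the alleles were made. The test was first run on both loci pooled and then split: within 10 Mb of either, 9 of 408 genes (2.21%) had a p under 0.01, against a 95th percentile of 1.66% over pairs of windows (as high in a share of 0.0243). Within 10 Mb of Prdm9, 8 of 147 genes (5.44%) had a p under 0.01, against a 95th percentile of 2.30% over 10000 windows around random genes (a share of 0.0046 of them was as high), among them Ermard, Acat3, Tagap and Dynlt1b higher in Prdm9 KO and Mrps34 lower. Within 10 Mb of Psmc3ip it was 1 of 261 genes (Cntnap1, 0.383%, as high in a share of 0.379 of windows), too few to decide, and 65 of the 74 placed genes with such a p lay in neither window. Reads shared with near-identical copies may play a part as well. Of the 17 genes with p under 0.001, 10 (58.8%) were pseudogenes or copies by name, against 3.77% of all tested genes (Fisher's exact test p = 8.3e-11), all 10 higher in Prdm9 KO. The test was chosen after these genes were seen, so its p describes the excess and does not weigh shared reads against other explanations. Strain differences, shared reads and an effect of the genotypes on these genes all remain open.

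Markers of Sertoli cells, Leydig cells and macrophages were higher in both knockouts than in adult wild type, as the loss of spermatids alone could bring about. Myoid and endothelial lists pointed the same way, but their calls were lost with quantile normalization and with rescaled columns. No list passed with an estimated correlation. Loss of spermatids alone would raise all types alike in the values, but on the log2 scale the added 1 moves weakly expressed genes less. The 5 list medians spanned 1.67 on that scale in Prdm9 KO (permutation p = 0.00066) and 1.49 in Hop2 KO (p = 0.00366, the permutation test too). The span ran from endothelial genes to macrophage or Leydig genes, and was 1.27 to 2.01 over other settings. In Prdm9 KO it was 1.38 with a pseudocount of 0.1 and 1.92 with 5. The permutation also takes genes as independent, so the span cannot decide whether loss of spermatids suffices. The lowest list was not fixed: it was myoid with a minimum mean of 5 (1.49 in Prdm9 KO, 1.42 in Hop2 KO) and in Hop2 KO with a pseudocount of 0.1 (1.27). A scaling factor common to all genes would move these lists with the median of all genes, but the Sertoli, Leydig and macrophage medians lay at least 2.11 above it. A factor per library leaves that difference nearly fixed, so of the scalings quantile normalization alone tested it anew, where it was at least 2.27. Loss of spermatids alone remains open. The age of the knockout mice and a change within the types that rose remain open and untested.

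Prdm9 K/K peaks lay at gene ends, where open chromatin could yield fragments unrelated to breaks. Double-stranded fragments alone would fall on both strands alike, but 80.5% of fragments left of the middle of peaks at gene ends were on the plus strand and 19.2% right of it. The split over all peaks had largely set this result, as gene-end peaks hold 231697 of the 348003 fragments left of the middles. It was therefore no separate test, and a part of double-stranded fragments is not excluded. Uneven recovery along chromosomes cannot be told apart from more breaks there: placements at fragments outside peaks reached at most 9.72%, but they leave out the fragments in peaks. Whether breaks or their recovery favour gene ends in this genotype remains open, from 1 library, with no break map of wild-type testis analysed here.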
